A study of Mus musculus with 50 samples.

How the data were processed

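RNA of 30 single mouse follicles (day 4 and day 6 at FSH 5, and day 6 at FSH 10, 20 and 30, 6 each) and of 20 single oocytes (10 each from follicles at FSH 10 and FSH 30) was measured. Per the labels' protocols, follicle libraries were made with a low-input mRNA method and oocyte libraries with Smart-Seq2 and Nextera XT, so that follicles and oocytes were never fitted together. Each library is 1 follicle or 1 oocyte, cultured per the labels 1 bead to a well. How many follicles a bead held and which animal each came from are not given in the sources used here, so that single follicles and oocytes served as replicates.

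The deposited values were estimated counts per gene and log2(TPM + 1) per gene, where the back-transformed TPM summed to 999998 to 1000003 in each library. The deposited estimated counts were not all whole numbers, with 79.3% (follicles) and 83.7% (oocytes) whole within 0.001, and were rounded for the count tests; the design written before had taken them for whole counts. Partek, Bowtie2, HISAT2, DESeq2 and the genome build mm10 are named per the submitters' processing notes, without role, order or version, and the annotation is not given in the sources used here. The tables listed 24139 genes for follicles and 17355 for oocytes, each with a summed count of at least 10, and 0 genes of the mitochondrial chromosome, so that the list of mitochondrially encoded respiratory chain genes was not tested. Spreadsheet dates stood in place of 25 and 20 gene symbols, all of which were restored from their coordinates. Gene starts were the same as in GENCODE M21 for 99.3% and 99.4% of genes. Without a stated strand setting, reads of overlapping or antisense genes and of near-identical copies, such as ribosomal protein pseudogenes, cannot be told apart.

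Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr by group and the quasi-likelihood F-test, two-sided, and Benjamini-Hochberg adjustment over all genes tested at a threshold of 0.05. All 30 follicles entered 1 fit of 5 groups, the dose trend used the 24 day 6 follicles with the log2 dose as the only term, and the oocytes had a fit of their own. Log2 CPM used a prior count of 2, which compresses the changes of low genes. The common biological coefficient of variation was 0.354 in follicles and 0.539 in oocytes. At the lowest depth, 1 read was worth 0.0741 CPM in follicles and 0.0916 CPM in oocytes.

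Gene lists for granulosa, luteal, steroid, cholesterol, cyclic AMP, theca, stroma, oocyte, immune, endothelial, mesothelial, metabolic, stress, cell cycle, ribosomal and meiotic genes were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Of 190 list tests 89 passed, 24 with an estimated correlation. The median, the mean and the camera direction differed in sign in 28, of which 0 had passed. Several genes stand in more than 1 list, among them Star, Cyp11a1, Cyp19a1, Hsd3b1, Cyp17a1 and Akr1c18.

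The groups, tests, gene lists, other settings to try and the rule for named genes were set before the data were examined. By that rule, named genes passed the threshold at a mean log2 CPM of at least 2, were not numbered gene models, and were the 10 with the highest and the 10 with the lowest log2 change in the main comparisons (5 and 5 in the others), with up to 4 members of each list and a fixed set of genes always reported. After the values were seen, genes under that mean level and numbered models were also passed over among the genes given as not passing, and genes whose call held when any 1 library was left out were preferred in the text. Those other settings were RLE size factors, a 2-fold minimum, no filter on low counts, the 12 libraries of a comparison alone, each library left out, DESeq2 1.42.0, limma 3.58.1 on log2(TPM + 1), the number of detected genes as a covariate, dose on the linear scale and a replicate block. Chosen after seeing the data were fits without the 4 follicles with fewer than 17000 detected genes, fits without the 3 oocytes with a TMM factor above 1.1 or fewer than 12500 detected genes, and counts at an unadjusted p.

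The fit was tested on simulated data with known changes. For 30 against 5 mIU/mL, edgeR recovered 54%, 66.7%, 70% and 76% of genes changed 1.5-fold, 2-fold, 3-fold and 4-fold among 16475 genes, with 4.1% of calls false. For the oocytes it recovered 6.1%, 25.5%, 68.8% and 89.4% among 10502 genes, with 5.2% of calls false, while 12.9% of the calls of DESeq2 were false among 10867 genes. Each comparison was simulated only once, with genes drawn independently and without libraries that stand apart, so that rates in the real data can differ. Of all pairs of libraries within a group, 0 held identical values. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared the tables and drew the plots. Results for some single genes are not reported here.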

Results

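Single ovarian follicles and single oocytes of CD-1 mice, an outbred strain, were sequenced to measure how the dose of follicle-stimulating hormone (FSH), the pituitary hormone that drives the growth of antral follicles, acted on follicles grown outside the ovary. Secondary follicles had been enclosed in alginate, 1 bead to a well, and cultured with FSH at 5 mIU/mL until day 4. From day 4 to day 6 the dose stayed at 5 mIU/mL or was raised to 10, 20 or 30 mIU/mL. RNA of single follicles was sequenced on day 4 and, for each of the 4 doses, on day 6, with 6 follicles in each of the 5 groups. Other follicles grown at 10 and 30 mIU/mL were given maturation medium with human chorionic gonadotropin (hCG), which acts on the luteinizing hormone (LH) receptor, at 1.5 IU/mL and epidermal growth factor at 10 ng/mL, and 10 single oocytes per dose were collected 16 h after hCG.

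Follicle libraries held 13489728 to 23892306 estimated counts and 16343 to 20350 detected genes, so that 1 read was worth 0.0741 CPM (counts scaled to a common library total) at the lowest depth. Of the 30 follicles, 4 had fewer than 17000 detected genes, namely day 4 replicates 2 and 8, day 6 FSH 5 replicate 3 and day 6 FSH 30 replicate 6. Day 4 follicles are not in the dose trend, so that leaving out these 4 removes only the day 6 ones there. None of the 4 is at FSH 10 or FSH 20, so that they enter 20 against 10 mIU/mL only through the shared fit. Oocyte libraries held 10913001 to 18261465 estimated counts and 11993 to 14211 detected genes. Levels are given as CPM, mean ± SD over 6 follicles or 10 oocytes, and changes as edgeR's fold change with a p adjusted over all genes tested. These p-values measure the spread between single follicles or single oocytes, because the labels do not say which animal each came from. On the first principal component, day 4 follicles lay between 39.4 and 130 and day 6 follicles at FSH 20 and FSH 30 between -47.2 and -18.4, while day 6 follicles at FSH 5 lay between -12.7 and 105 and those at FSH 10 between -32.8 and -4.21. FSH 5 thus overlapped with day 4, through replicate 3 at 105, and with FSH 10, and FSH 10 overlapped with the higher doses. Oocytes of the 2 doses overlapped as well.

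**Figure D1:**
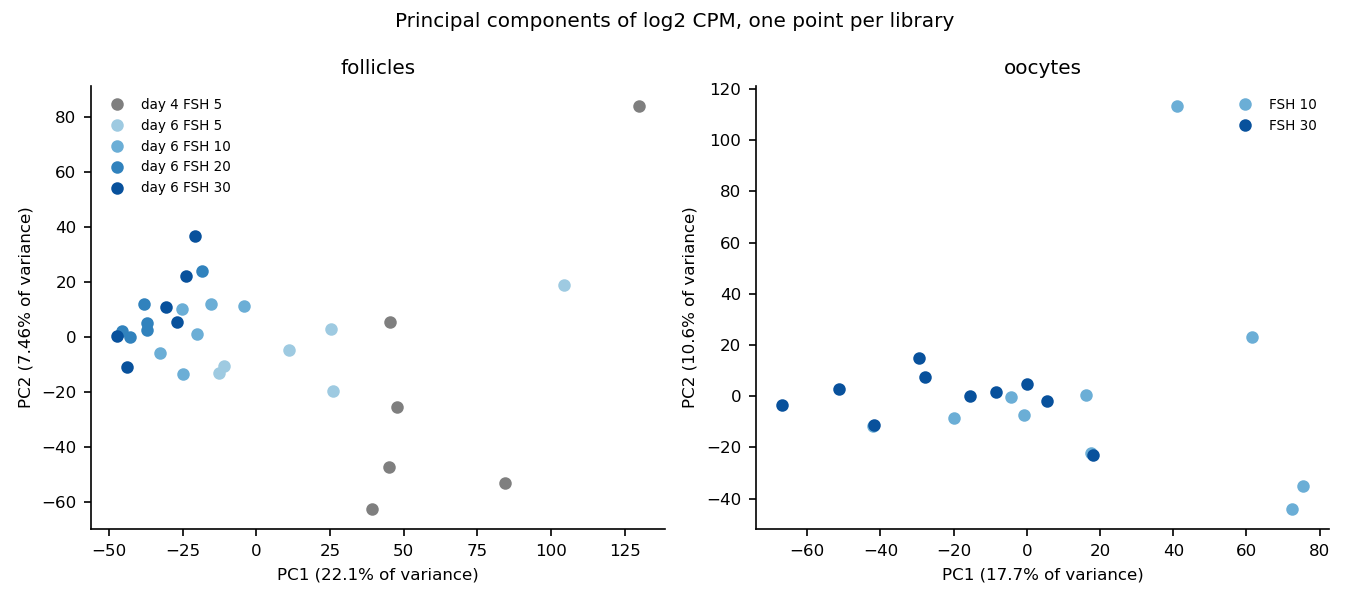
First and second principal components of log2 CPM for the 30 follicles (left) and the 20 oocytes (right), 1 point per library, coloured by group, with the percentage of the variance on each axis. In follicles, the second component took 7.46% of the variance.

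When follicles were kept at 5 mIU/mL for 2 more days, Comp, a cartilage matrix protein, rose 17.4-fold, from 15.3 ± 10.3 CPM on day 4 to 266 ± 224 CPM on day 6 (SD, n = 6, adjusted p = 0.000415). The somatostatin receptor gene Sstr1 rose 20.95-fold and the membrane lectin gene Clec14a rose 10.5-fold (adjusted p = 0.00042 and 0.000365). Inhba, which encodes the subunit of activins and of inhibin A, rose 1.99-fold to 7243 ± 2576 CPM (adjusted p = 0.0126). Comp, Sstr1, Clec14a and Inhba were higher in 5 of 6 follicles against the day 4 mean. Pappa, a protease that frees insulin-like growth factors from a binding protein, rose 5.37-fold, and Dlk1, which encodes a membrane protein related to Notch ligands, rose 7.69-fold (adjusted p = 0.00483 and 0.00691, 6 of 6 follicles). Of genes that fell in 6 of 6 follicles, Slc38a3, a glutamine transporter, decreased from 207 ± 129 to 63.8 ± 25.6 CPM (adjusted p = 0.00835), and the asparagine synthetase gene Asns from 52.5 ± 32.8 to 17.4 ± 5.27 CPM (adjusted p = 0.00199). The transcription factor Atf4, which drives amino acid starvation genes, fell by 0.74 on the log2 scale, and its target Chac1 fell by 3.72 (adjusted p = 0.000708 and 0.00413, 6 of 6 follicles). Without day 4 replicate 4 Sstr1 rose 44.4-fold, without day 4 replicate 3 Chac1 fell by 3.10, and without day 6 FSH 5 replicate 4 Pappa rose 2.55-fold (adjusted p = 0.027).

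By edgeR, 1082 of 16873 genes changed from day 4 to day 6 at FSH 5, 586 upward and 496 downward, and by at least 2-fold 145 rose and 41 fell. With limma on log2(TPM + 1) (TPM, the same after scaling by gene length), 1384 genes changed, 81.4% of them higher against 54.2% by edgeR. The count was 614 without day 4 replicate 2, 1694 without day 4 replicate 7, and 536, 2154, 534 and 595 without day 6 FSH 5 replicates 2, 3, 4 and 6. It was 313 with the number of detected genes as a covariate and 93 in a fit of only these 12 follicles, of which 29 were higher and 64 lower. Lhcgr, the LH receptor, rose 3.26-fold (adjusted p = 0.0395, 5 of 6 follicles). This call ended, at adjusted p of 0.054 to 0.146, without any 1 of day 4 replicates 2, 4 and 7 and day 6 FSH 5 replicates 2, 4 and 6. Among the other genes always reported, the changes of Cyp19a1 (log2 change 1.05, adjusted p = 0.0651), Cyp11a1 (0.65, 0.445), Star (0.14, 0.902), Inha (0.14, 0.41), Fshr (0.28, 0.425), Cyp17a1 (-0.21, 0.88) and Pgr (-0.49, 0.713) did not pass. Amh, which small growing follicles express, stood at 51.9 ± 28.3 CPM on day 4 and 8.03 ± 10.2 CPM on day 6, lower in 6 of 6 follicles, at an adjusted p of 0.107.

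Among lists fixed before the data were examined, the cell cycle genes fell from day 4 to day 6. Of 27 tested, 21 fell over all genes and 25 when adjusted over the list alone, with none higher, and the set test gave adjusted p = 3.2e-22 (adjusted p = 0.12 with an estimated correlation). Its members included Mcm4 and Mcm7, subunits of the replicative helicase, which fell by 0.72 and 0.58 on the log2 scale, and the spindle genes Tpx2 and Kif11, which fell by 0.46 and 0.50 (6 of 6 follicles each). Of 86 ribosomal protein genes, 33 fell over all genes and 67 when adjusted over the list alone (set test adjusted p = 6.9e-28, adjusted p = 0.27 with an estimated correlation), with Rps6 falling by 0.51 on the log2 scale. Without the 4 follicles with few detected genes, 23 cell cycle and 46 ribosomal protein genes fell. On log2(TPM + 1), limma called 9 and 20 of them lower, and with the number of detected genes as a covariate edgeR called 4 cell cycle genes lower, at a median log2 change of -0.39 against -0.44 without it. Of 18 FSH-induced granulosa genes, 7 rose, 10 when adjusted over the list alone (adjusted p = 0.00088, adjusted p = 0.39 with an estimated correlation).

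Of 14 genes of the unfolded protein and integrated stress responses, 3 fell from day 4 to day 6, both over all genes and when adjusted over the list alone, namely Atf4, Asns and Chac1 (adjusted p = 0.0031, adjusted p = 0.37 with an estimated correlation). No member of the glycolysis and hypoxia lists passed over all genes by edgeR, while 2 of 15 and 4 of 11 were higher when adjusted over the list alone. Their set tests gave adjusted p = 0.00099 and 0.0013 (adjusted p = 0.67 and 0.48 with an estimated correlation). Markers of the oocyte within the follicle took 0.0675 ± 0.0101% of the counts on day 4 and 0.0564 ± 0.0311% on day 6 at FSH 5 (set test adjusted p = 0.00024, adjusted p = 0.65 with an estimated correlation). Of the 23 tested, 1 fell over all genes, Bmp15, and 0 when adjusted over the list alone. The call on Bmp15 ended without any 1 of day 4 replicates 3, 6 and 8 and day 6 FSH 5 replicates 2, 4, 5 and 6, at adjusted p of 0.0566 to 0.114. Nuclear genes of the respiratory chain had 1 of 23 lower over all genes and 0 when adjusted over the list alone (set test adjusted p = 0.0013, adjusted p = 0.65 with an estimated correlation). When the 4 follicles with few detected genes were left out, 2 glycolysis and 2 hypoxia genes rose, and 4 oocyte markers and 3 respiratory chain genes fell, over all genes.

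**Figure D2:**
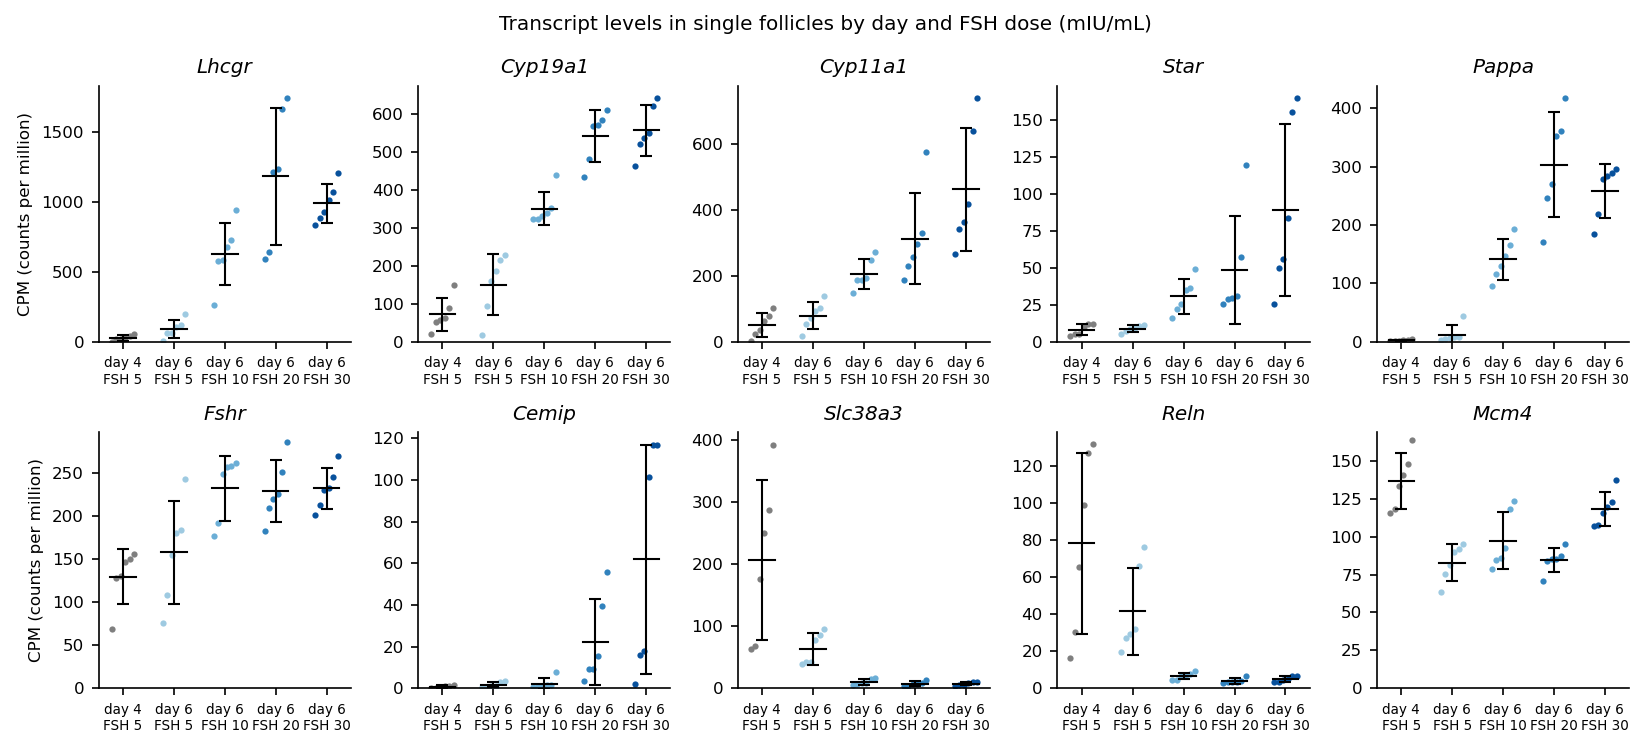
CPM of 10 genes in single follicles by day and FSH dose in mIU/mL, 1 point per follicle, with bars for the mean ± SD of 6 follicles. Lhcgr had means of 92.8, 628, 1182 and 990 CPM on day 6 at 5, 10, 20 and 30 mIU/mL, and Slc38a3 had means of 63.8, 10.2, 7.32 and 7.25 CPM.

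Raising FSH from 5 to 10 mIU/mL on day 4 raised the transcripts of gonadotropin response and steroid synthesis by day 6. Lhcgr, the LH receptor (mm10 chromosome 17, 88716481 to 88791990), rose 6.76-fold, from 92.8 ± 65.2 to 628 ± 224 CPM (SD, n = 6, adjusted p = 0.0016). Pappa (chromosome 4, 65124174 to 65357509) rose 11.4-fold, from 12.4 ± 15.9 to 141 ± 35.3 CPM (adjusted p = 1.9e-05), and 23.6-fold without day 6 FSH 5 replicate 4. The epidermal growth factor-like ligand Ereg rose 12.9-fold (adjusted p = 0.00158), and Star, which moves cholesterol into mitochondria (chromosome 8, 25806555 to 25815982), rose 3.47-fold to 30.7 ± 11.8 CPM (adjusted p = 0.0102). Fdx1, the electron donor of mitochondrial steroid enzymes, rose 2.67-fold to 141 ± 18.5 CPM (adjusted p = 5.9e-06). Inha, the inhibin alpha subunit, rose 1.46-fold to 11970 ± 1587 CPM (adjusted p = 0.000506), and Cyp17a1, the enzyme that makes androgens in theca cells, rose 5.03-fold (adjusted p = 0.0109). The endocytic receptor Lrp2 rose 5.58-fold and the transcription factor Zbtb16 4.29-fold (adjusted p = 0.00516 and 0.00646). Each of these genes was higher than the FSH 5 mean in 6 of 6 follicles at FSH 10.

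Genes that fell at 10 against 5 mIU/mL included Slc38a3 (chromosome 9, 107650634 to 107669530), from 63.8 ± 25.6 to 10.2 ± 4.49 CPM, and Reln, which encodes the secreted glycoprotein reelin, from 41.7 ± 23.4 to 6.74 ± 1.79 CPM (adjusted p = 0.000187 and 0.000167). The transcription factor gene Atoh8 fell by 4.17 on the log2 scale, the netrin gene Ntn4 by 3.27 and Fgd5, which encodes an exchange factor of small GTPases, by 2.95 (adjusted p = 0.000698, 0.000323 and 0.00365). The glycosyltransferase gene Galnt15 fell by 2.82 and the phosphodiesterase-like gene Gdpd2 by 2.22 (adjusted p = 0.00233 and 0.00446). All were lower than the FSH 5 mean in 6 of 6 follicles. By edgeR, 752 of 16873 genes changed, 404 upward and 348 downward, and by at least 2-fold 71 rose and 104 fell. With limma on log2(TPM + 1), 705 genes changed, of which 31.9% were higher against 53.7% by edgeR. The count was 421 without day 6 FSH 5 replicate 3, 411 without replicate 7 of that group and 492 without day 6 FSH 10 replicate 6.

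Cyp19a1, the aromatase that makes estradiol (chromosome 9, 54165937 to 54268110), rose 2.33-fold at 10 against 5 mIU/mL (adjusted p = 0.0389, 6 of 6 follicles). This call ended, at adjusted p of 0.0539 to 0.108, when day 6 FSH 5 replicate 2 or 7 or any 1 of the 6 follicles at FSH 10 was left out. Fshr, the FSH receptor (chromosome 17, 88984952 to 89200675), stood at 158 ± 59.4 and 232 ± 37.5 CPM (adjusted p = 0.0938, higher in 6 of 6 follicles). Cyp11a1, which cleaves the cholesterol side chain, stood at 79.9 ± 41.1 and 207 ± 45.3 CPM (adjusted p = 0.0862, 6 of 6 follicles). The log2 changes of Inhba (0.37, adjusted p = 0.451), Amh (-0.67, 0.807) and Pgr (0.21, 0.914) did not pass either.

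The lists of gonadotropin and sterol genes moved together at 10 against 5 mIU/mL. Of 23 genes of cholesterol synthesis and uptake, 11 rose over all genes and 22 when adjusted over the list alone, with none lower (set test adjusted p = 2.8e-16). They included the lanosterol demethylase Cyp51, up 1.37-fold in 6 of 6 follicles. Of 15 genes of steroid synthesis, 6 rose, 11 when adjusted over the list alone (adjusted p = 1.3e-10). Of 23 LH-response and luteal genes, 7 rose, 9 when adjusted over the list alone, Adamts1 and Prlr by 2.34-fold and 1.97-fold (adjusted p = 3.1e-06). Of 18 FSH-induced granulosa genes, 8 rose and 1 fell, the estrogen receptor Esr2, by 0.81 on the log2 scale; adjusted over the list alone the counts were 11 and 1 (adjusted p = 7.9e-08). Of 12 genes of the early response to cyclic AMP, the second messenger of the FSH receptor, 3 rose, 7 when adjusted over the list alone (adjusted p = 4.9e-06). Of 14 unfolded protein and stress response genes, 4 rose, 9 when adjusted over the list alone, among them the chaperones Calr and Hspa5, 1.29-fold and 1.21-fold (adjusted p = 7.9e-08). These 6 set tests also passed with an estimated correlation, at adjusted p of 0.0097 to 0.037. Cell cycle genes had 0 of 27 passing, over all genes by edgeR and when adjusted over the list alone (set test adjusted p = 0.0883). Without the 4 follicles with few detected genes, 6 early cyclic AMP response genes rose over all genes and the cell cycle set test gave adjusted p = 0.0016 (adjusted p = 0.56 with an estimated correlation).

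Follicles at 20 and 30 mIU/mL, set against those at 5 mIU/mL, also had higher gonadotropin response and steroid synthesis transcripts. Lhcgr stood at 1182 ± 488 CPM at FSH 20 and 990 ± 138 CPM at FSH 30, 12.7-fold and 10.7-fold above FSH 5 (adjusted p = 3.2e-05 and 4.5e-05). Cyp19a1 rose 3.6-fold and 3.7-fold, to 541 ± 68.4 and 556 ± 65.9 CPM (adjusted p = 0.000793 and 0.000436), Cyp11a1 3.93-fold and 5.8-fold (0.00595 and 0.000447), and Star 5.52-fold and 10.1-fold, to 48.7 ± 36.5 and 89.1 ± 58 CPM (0.000228 and 4.5e-06). Cemip, a hyaluronan-binding protein (chromosome 7, 83932857 to 84086502), rose 12.8-fold and 35.7-fold, Ptgfr, the receptor of the luteolytic prostaglandin, 9.9-fold and 26.6-fold, and Akr1c18, the luteal enzyme that inactivates progesterone, 27.7-fold at FSH 30 (adjusted p = 0.00145). Atoh8 fell by 4.55 and 3.71 on the log2 scale, and at FSH 30 Nos2, the inducible nitric oxide synthase, fell by 3.19 (adjusted p = 7.6e-05). Against the FSH 5 mean, all of these genes lay on the side of their change in 6 of 6 follicles. Single follicles could still overlap, as for Cemip, at 2.255 CPM in FSH 30 replicate 7 and 3.636 CPM in FSH 5 replicate 3. At FSH 30, Akr1c18 rose 41.6-fold without day 6 FSH 5 replicate 2, and Nos2 fell by 2.52 without replicate 3 of that group. Fshr (1.45-fold and 1.47-fold, adjusted p = 0.0751 and 0.0521) and Inhba (1.49-fold and 1.14-fold, 0.14 and 0.673) did not pass. Amh and Pgr did not pass at FSH 30 either (log2 changes -0.46 and 0.37, adjusted p = 0.826 and 0.763).

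By edgeR, 1561 genes changed at 20 against 5 mIU/mL, 835 upward and 726 downward, and 2152 at 30 against 5 mIU/mL, 1137 upward and 1015 downward. With limma on log2(TPM + 1), 2449 genes changed at FSH 30, 35.2% of them higher against 52.8% by edgeR. The count at FSH 20 was 1002 without day 6 FSH 5 replicate 3 and 1019 with the number of detected genes as a covariate. At FSH 30, 22 of 23 cholesterol genes rose, over all genes and when adjusted over the list alone (set test adjusted p = 8.8e-21), as did 15 of 23 LH-response and luteal genes, again with either adjustment (8e-13). Of 15 steroid synthesis genes 11 rose, 13 when adjusted over the list alone (adjusted p = 5.3e-13). Of 12 early cyclic AMP response genes 9 rose, 11 when adjusted over the list alone (5.1e-12), with the nuclear receptors Nr4a1 and Nr4a3 up 4.24-fold and 8.52-fold. Those 4 set tests gave adjusted p of 5.4e-05 to 0.0078 with an estimated correlation. Of 18 FSH-induced granulosa genes, 10 rose and 1 fell, 11 and 1 when adjusted over the list alone (adjusted p = 2.2e-06, adjusted p = 0.069 with an estimated correlation). Of 27 cell cycle genes 3 rose with either adjustment, all helicase subunits, Mcm4 and Mcm3 by 1.43-fold each in 6 of 6 follicles, and Mcm2 (set test adjusted p = 0.016, adjusted p = 0.68 with an estimated correlation). The rise of Mcm2, 1.31-fold at adjusted p = 0.0403, ended without any 1 of day 6 FSH 5 replicates 2, 4, 5, 6 and 7 and FSH 30 replicates 1, 5, 6 and 7, at adjusted p of 0.0503 to 0.142.

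**Figure D3:**
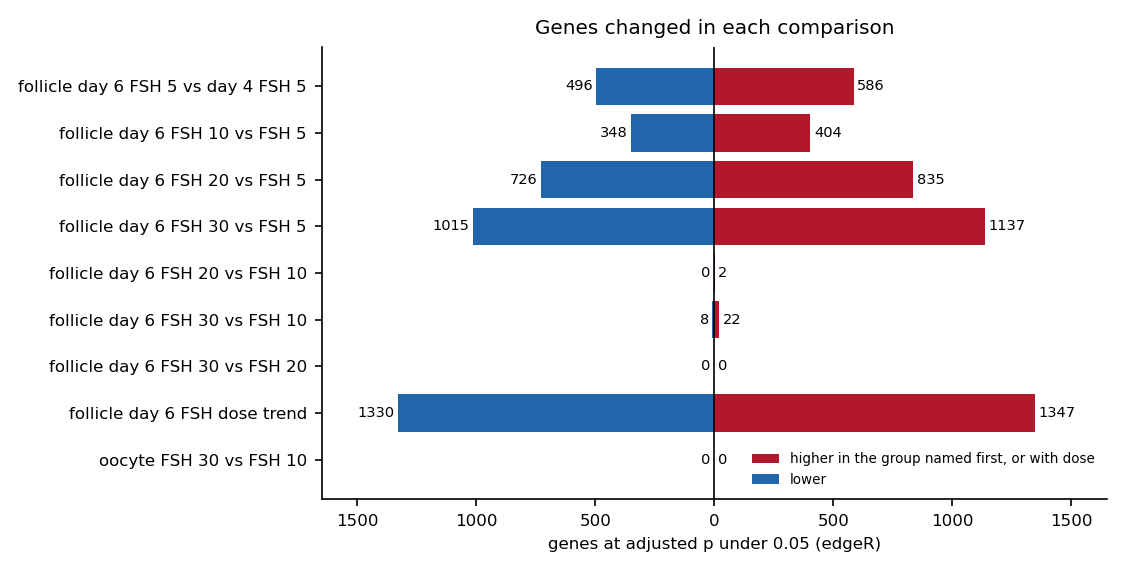
Number of genes higher and lower at adjusted p under 0.05 by edgeR in each comparison. The counts ran from 0 in the oocytes and at 30 against 20 mIU/mL to 2152 at 30 against 5 mIU/mL and 2677 in the dose trend.

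Between the raised doses, few single genes separated. At 30 against 10 mIU/mL, Cemip rose 27.2-fold, from 2.27 ± 2.66 to 61.8 ± 55 CPM (SD, n = 6, adjusted p = 0.0107, 5 of 6 follicles), and 51.2-fold without FSH 10 replicate 2. Epdr1, an ependymin-related gene, rose 2.51-fold, from 27.3 ± 3.99 to 68.5 ± 16.4 CPM (adjusted p = 0.00284, 6 of 6). Fdx1 rose 2.1-fold to 296 ± 49.3 CPM (adjusted p = 0.00284, 6 of 6), and Me3, a mitochondrial malic enzyme, fell from 57.3 ± 5.66 to 37.9 ± 4.22 CPM (adjusted p = 0.0107, 6 of 6). In all, 30 genes changed by edgeR, 22 upward and 8 downward, while 100 changed without the 4 follicles with few detected genes, 92 by DESeq2 and 108 in a fit of the 12 follicles alone. The count was 8, 8, 18 and 11 without FSH 10 replicates 1, 4, 5 and 6, 16 and 10 without FSH 30 replicates 4 and 5, and 52 without day 4 replicate 8. The Wnt antagonist gene Sfrp4 rose 9.49-fold and Nr4a3 4.81-fold (adjusted p = 0.0211 each, 6 of 6). Neither call held, at adjusted p of 0.0514 to 0.077, without any 1 of FSH 10 replicates 1, 4, 6 and 7 and FSH 30 replicates 4 and 5, nor Sfrp4's without FSH 10 replicate 5 or Nr4a3's without FSH 10 replicate 2. Star, at 30.7 ± 11.8 and 89.1 ± 58 CPM, did not pass (adjusted p = 0.134, 5 of 6), nor did Cyp11a1 (2.24-fold, 0.507), Cyp17a1 (1.91-fold, 0.77), Cyp19a1 (1.58-fold, 0.743), Lhcgr (1.58-fold, 0.902) or Fshr (log2 change 0.00, 0.999).

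As a list, LH-response and luteal genes were higher at 30 than at 10 mIU/mL. Over all genes 1 of the 23 rose, Sfrp4, and 7 when adjusted over the list alone, and the set test gave adjusted p = 1.7e-09 (adjusted p = 0.00046 with an estimated correlation). Of the 12 early cyclic AMP response genes, 1 rose, Nr4a3, and 8 when adjusted over the list alone (adjusted p = 1.6e-09, adjusted p = 0.01 with an estimated correlation). Of 15 steroid synthesis genes 1 rose over all genes, Fdx1, and 3 when adjusted over the list alone, and of 23 cholesterol genes 0 and 4 (set test adjusted p = 1.5e-05 and 2e-08, adjusted p = 0.2 for each with an estimated correlation). The FSH-induced granulosa list had 0 of 18 passing over all genes and 1 when adjusted over the list alone (adjusted p = 0.484). When the 4 follicles with few detected genes were left out, 6 LH-response, 3 cyclic AMP response, 2 steroid synthesis, 1 cholesterol and 1 FSH-induced gene rose over all genes. At 20 against 10 mIU/mL, 2 genes passed, the calcium channel gene Cacna1h (1.79-fold) and Fdx1 (1.87-fold), each at adjusted p = 0.0361 and in 6 of 6 follicles. Neither call held without any 1 of day 6 FSH 5 replicates 6 and 7, FSH 10 replicates 2, 4, 5, 6 and 7 and FSH 20 replicates 4, 7 and 8, where the adjusted p was 0.0508 to 0.164. The call on Cacna1h also ended without FSH 20 replicate 5 (0.144), and that on Fdx1 without FSH 10 replicate 1 (0.143). The count was 0 by limma, with the number of detected genes as a covariate, in a fit of the 12 follicles alone and without the 4 follicles with few detected genes. At 30 against 20 mIU/mL, 0 genes passed by edgeR, limma and DESeq2, with 756 at an unadjusted p under 0.05, 435 of them higher, and 13 passed in a fit of the 12 follicles alone. The smallest adjusted p was 0.638, shared by Mcm4, at 84.6 ± 8.01 and 118 ± 11.2 CPM, and 3 other genes. For this pair, the LH-response and luteal list had 0 of 23 genes higher over all genes and 1 when adjusted over the list alone (set test adjusted p = 3.6e-05, adjusted p = 0.025 with an estimated correlation). The latter was 0.0508 without the 4 follicles with few detected genes.

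Across the 24 day 6 follicles, a slope on the log2 dose was fitted from 5 to 30 mIU/mL. Such a slope can pass for a single step between 5 and 10 mIU/mL as well as for a graded change, and which it was was not tested. Between the raised doses, 2 genes passed at 20 against 10 mIU/mL, 30 at 30 against 10 and 0 at 30 against 20. Folds below are those of the fitted slope from 5 to 30 mIU/mL. Cemip rose 48.7-fold over this range, with a slope of 2.17 ± 0.30 (SE) per doubling (adjusted p = 1.5e-05), Ptgfr 23.4-fold, Akr1c18 24.05-fold, Pappa 17.5-fold, Ereg 17.2-fold, Sfrp4 15.95-fold and Lhcgr 10.3-fold. Star rose 8.59-fold (slope 1.20 ± 0.16, adjusted p = 6.9e-06), Cyp11a1 5.33-fold (0.93 ± 0.12, 7.3e-06), Fdx1 5.71-fold, Cyp19a1 3.74-fold (0.74 ± 0.12, 0.000118) and Inha 1.5-fold (0.22 ± 0.04, 0.000418). Among the genes that fell, Prss23, a secreted serine protease, had a slope of -0.98 ± 0.07 (adjusted p = 1.7e-09), with means of 622, 196, 128 and 106 CPM at 5, 10, 20 and 30 mIU/mL. Reln, Slc38a3, Gdpd2 and Nos2 fell by 1.23, 1.22, 1.24 and 1.16 per doubling on the log2 scale (adjusted p = 1.2e-06, 1.4e-06, 3.5e-06 and 2.7e-05). Without FSH 5 replicate 3, Sfrp4 rose 31.9-fold and Nos2 fell by 0.88 per doubling. Fshr (1.41-fold, adjusted p = 0.0621), Inhba (1.23-fold, 0.312), Pgr (1.22-fold, 0.713) and Amh (slope -0.21, 0.757) did not pass. In all, 2677 of 16454 genes changed by edgeR, 1347 with a positive and 1330 with a negative slope, and by limma on log2(TPM + 1) 2935 changed, 40.3% of them with a positive slope.

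Sterol, steroid and gonadotropin response lists rose along the dose. Of 23 cholesterol genes 22 rose with dose, 23 when adjusted over the list alone (set test adjusted p = 1.7e-17). Of 15 steroid synthesis genes 11 rose, 13 when adjusted over the list alone (3.4e-12). Of 23 LH-response and luteal genes 15 rose, 16 when adjusted over the list alone (8.9e-12), and of 12 early cyclic AMP response genes 10, 11 when adjusted over the list alone (3.4e-12). With an estimated correlation these 4 lists had adjusted p of 0.00032 to 0.031. For cholesterol genes it was 0.058 without the 4 follicles with few detected genes. Of 18 FSH-induced granulosa genes 9 rose and 1 fell, 10 and 1 when adjusted over the list alone (adjusted p = 7.8e-06, adjusted p = 0.14 with an estimated correlation). Of 15 glycolysis genes 6 rose, 11 when adjusted over the list alone, Gpi1 and Pkm by 1.45-fold and 1.64-fold (adjusted p = 1.1e-05, adjusted p = 0.33 with an estimated correlation), and 11 rose over all genes without those 4 follicles. Of 14 unfolded protein and stress response genes 5 rose, 7 when adjusted over the list alone (adjusted p = 7.1e-05, adjusted p = 0.08 with an estimated correlation). Immature granulosa genes went both ways, Igfbp5 and Gatm up 2.89-fold and 2.72-fold and 4 others of 12 down, such as Pik3ip1, which fell by 0.70 per doubling on the log2 scale (3 up and 4 down when adjusted over the list alone, set test adjusted p = 0.8).

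The antioxidant, apoptosis, hypoxia, cytokine, respiratory chain, heat shock, ribosomal protein and cell cycle lists had 2 to 5 members passing over all genes along the dose. Of 16 antioxidant genes 3 rose with either adjustment, Srxn1, which repairs peroxiredoxins, by 3-fold (set test adjusted p = 0.048, adjusted p = 0.33 with an estimated correlation). Of 15 apoptosis genes cytochrome c (Cycs) rose 1.35-fold and Trp53 fell by 0.19 per doubling, with either adjustment (adjusted p = 0.8). Hypoxia genes had 2 of 11 higher, 4 when adjusted over the list alone, with Ndrg1 up 4.2-fold, and inflammatory cytokines 2 of 7 with either adjustment (adjusted p = 0.0037 and 0.024, adjusted p = 0.33 for each with an estimated correlation). Nuclear respiratory chain genes had 2 of 23 higher, 1 when adjusted over the list alone (0.048, adjusted p = 0.64 with an estimated correlation). Immediate-early and heat shock genes had 2 of 13 higher and 1 lower, 3 and 1 when adjusted over the list alone (adjusted p = 0.87). Of 86 ribosomal protein genes 5 fell, 0 when adjusted over the list alone (adjusted p = 0.0001, adjusted p = 0.61 with an estimated correlation). Of 27 cell cycle genes 2 rose, 0 when adjusted over the list alone (0.293). Without the 4 follicles with few detected genes, the set tests of antioxidant and respiratory chain genes no longer passed (adjusted p = 0.15 and 0.252), with 2 higher, and with 1 higher and 1 lower. That of cell cycle genes gave adjusted p = 0.0398 with 0 members passing by edgeR (adjusted p = 0.72 with an estimated correlation). In the same fit, 6 hypoxia genes, 1 cytokine and 1 immediate-early or heat shock gene rose, and 0 ribosomal protein genes fell.

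**Figure D4:**
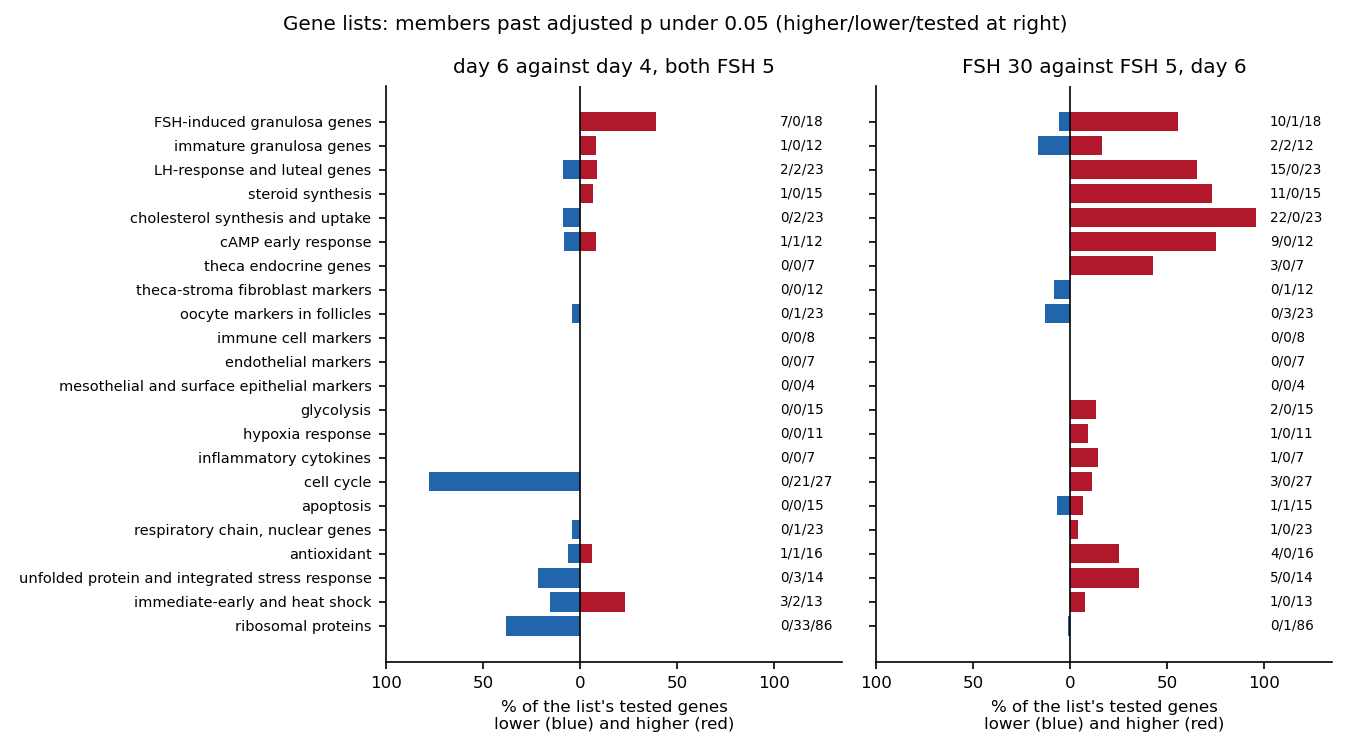
Percentage of each list's tested members that were higher (right of 0) or lower (left of 0) at adjusted p under 0.05 over all genes by edgeR, for day 6 against day 4 at FSH 5 and for 30 against 5 mIU/mL on day 6. Cell cycle genes had 21 of 27 members lower in the first comparison and 3 higher in the second, and cholesterol genes had 2 lower in the first and 22 of 23 higher in the second.

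Markers of cell types other than granulosa cells moved in part with the dose. The 7 genes of the theca endocrine list, named for the androgen-making cells around the granulosa layer, took 0.408 ± 0.0909% of the counts on day 6 at FSH 5. At 10, 20 and 30 mIU/mL they took 0.525 ± 0.0204%, 0.527 ± 0.0276% and 0.548 ± 0.0425%. Most of this share was Hsd3b1, which also stands in the cumulus and granulosa list, so that the share cannot be read as that of theca cells alone. Hsd3b1 and Cyp17a1 stand in the steroid synthesis list as well. Hsd3b1, a steroid dehydrogenase gene, took 0.357 ± 0.0754, 0.440 ± 0.0227, 0.434 ± 0.0107 and 0.427 ± 0.0279% of the counts, and the other 6 genes 0.0506 ± 0.0189, 0.0848 ± 0.0156, 0.0930 ± 0.0299 and 0.121 ± 0.0221%. Of these 7, Cyp17a1, Insl3 and Aldh1a1 rose with dose, 7.54-fold, 6.72-fold and 2.35-fold, 4 when adjusted over the list alone (set test adjusted p = 0.0014, adjusted p = 0.33 with an estimated correlation). Of 12 theca-stroma fibroblast markers 3 rose and 1 fell with either adjustment (adjusted p = 0.726), with the collagen-producing cell marker Pdgfra up 1.8-fold and the contractile gene Tagln falling by 0.86 per doubling. These 12 markers took 0.130 ± 0.0477, 0.155 ± 0.0572, 0.164 ± 0.0575 and 0.189 ± 0.0611% of the counts at 5, 10, 20 and 30 mIU/mL. Oocyte markers took 0.0564 ± 0.0311, 0.0426 ± 0.0222, 0.0354 ± 0.00872 and 0.0494 ± 0.0231% at 5, 10, 20 and 30 mIU/mL. Of the 23, 5 fell along the dose by either adjustment, such as Oog1, which fell by 0.34 per doubling (adjusted p = 0.024, adjusted p = 0.64 with an estimated correlation). When the 4 follicles with few detected genes were left out, 1 fell, the median slope was 0.009 and the set test did not pass (adjusted p = 0.354). Immune, endothelial and mesothelial markers had 0 members passing by edgeR along the dose, over all genes or adjusted over the list alone (set test adjusted p = 0.18, 0.13 and 0.22). They took at most 0.00219%, 0.0103% and 0.000506% of a group's counts on average.

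In oocytes 16 h after hCG, no gene separated those from follicles at 30 mIU/mL from those at 10 mIU/mL after adjustment. Gdf9, the growth factor oocytes send to cumulus cells (chromosome 11, 53431023 to 53437904), stood at 7044 ± 2014 CPM at FSH 10 and 6243 ± 868 CPM at FSH 30 (SD, n = 10, adjusted p = 0.555). Its partner Bmp15 stood at 2820 ± 1299 and 2720 ± 606 CPM (0.92). Zp3, the sperm-binding zona protein, stood at 773 ± 334 and 545 ± 97.7 CPM (adjusted p = 0.221, 10 of 10 oocytes below the FSH 10 mean). Btg4, which drives decay of maternal mRNA, stood at 8183 ± 1741 and 10880 ± 2323 CPM (0.195, 8 of 10 above). Mos, the kinase of meiotic arrest, stood at 1659 ± 404 and 1392 ± 342 CPM (0.418), cyclin B1 (Ccnb1) at 5326 ± 1818 and 5868 ± 1460 CPM (0.74), and the maternal-effect gene Nlrp5 at 956 ± 560 and 734 ± 365 CPM (0.546). Inhba had too few counts to be tested, with 130 and 123 counts over the 10 oocytes of each dose. The smallest adjusted p was 0.183, for genes that included Rims3, at 24.5 ± 8.52 and 10.4 ± 3.57 CPM, and Ttc5, at 28.3 ± 15.9 and 10.4 ± 3.91 CPM. Others at this value were Armc7, at 9.83 ± 4.51 and 3.52 ± 1.81 CPM, Ap1m1, at 118 ± 37.6 and 62.8 ± 20.5 CPM, and Fzr1, an activator of the anaphase-promoting complex, at 46.3 ± 32.2 and 15.4 ± 5.28 CPM. All of these genes were below the FSH 10 mean in 10 of 10 oocytes.

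By edgeR, 0 of 10867 genes passed in oocytes, with 1733 at an unadjusted p under 0.05, 745 of them higher and 988 lower. The count was 0 by limma, 111 by DESeq2, 36 without FSH 10 replicate 11 and 5 without FSH 30 replicate 9. Each of the 14 lists tested had 0 members passing over all genes by edgeR. Ribosomal protein genes had a median log2 change of -0.46 over 78 genes, 0 of them passing when adjusted over the list alone, and a set test at adjusted p = 4e-07 (adjusted p = 0.43 with an estimated correlation), with Rps3 at a log2 change of -1.28. Across genes, which are not independent replicates, the log2 change in oocytes correlated with GC content (Pearson's r = -0.46). Nuclear respiratory chain genes had a median of -0.33 over 23 genes, 0 passing when adjusted over the list alone (adjusted p = 0.01, adjusted p = 0.43 with an estimated correlation). Without the 3 oocytes at FSH 10 that stood apart in scaling factor or detected genes (replicates 3, 5 and 13), the adjusted p of the ribosomal and respiratory chain lists were 0.0538 and 0.42 and the medians -0.21 and -0.14.

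The other oocyte lists did not pass a set test. Adjusted over the list alone, 2 of 10 oocyte-secreted and zona genes were higher, Oosp1 and Oosp3, and 4 lower (set test adjusted p = 0.32). Likewise, 2 of 22 maternal-effect genes, Tle6 and Khdc3, were lower (0.073). So were 2 of 6 immediate-early and heat shock genes (0.41), 1 of 27 cell cycle genes (0.62) and 1 of 14 antioxidant genes (0.18). Adjusted over the list alone, 0 passed by edgeR among 25 meiosis and maturation genes (0.39), 20 genes of maternal mRNA decay and translation (0.41), 15 DNA repair genes (0.17), 18 spindle and kinetochore genes (0.18), 11 apoptosis genes (0.84) and 10 unfolded protein and stress response genes (0.18). The 4 cumulus and granulosa markers tested had 0 passing with either adjustment (set test adjusted p = 0.18) and a median log2 change of -0.16, which was 0.33 on log2(TPM + 1). The full cumulus and granulosa list took 0.181 ± 0.0452% of the counts at FSH 10 and 0.208 ± 0.0512% at FSH 30. Serpine2 alone, a protease inhibitor gene, took 0.173 ± 0.0427% and 0.2002 ± 0.0521%, and the other 12 genes 0.00766 ± 0.00326% and 0.00745 ± 0.00225%.

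**Figure D5:**
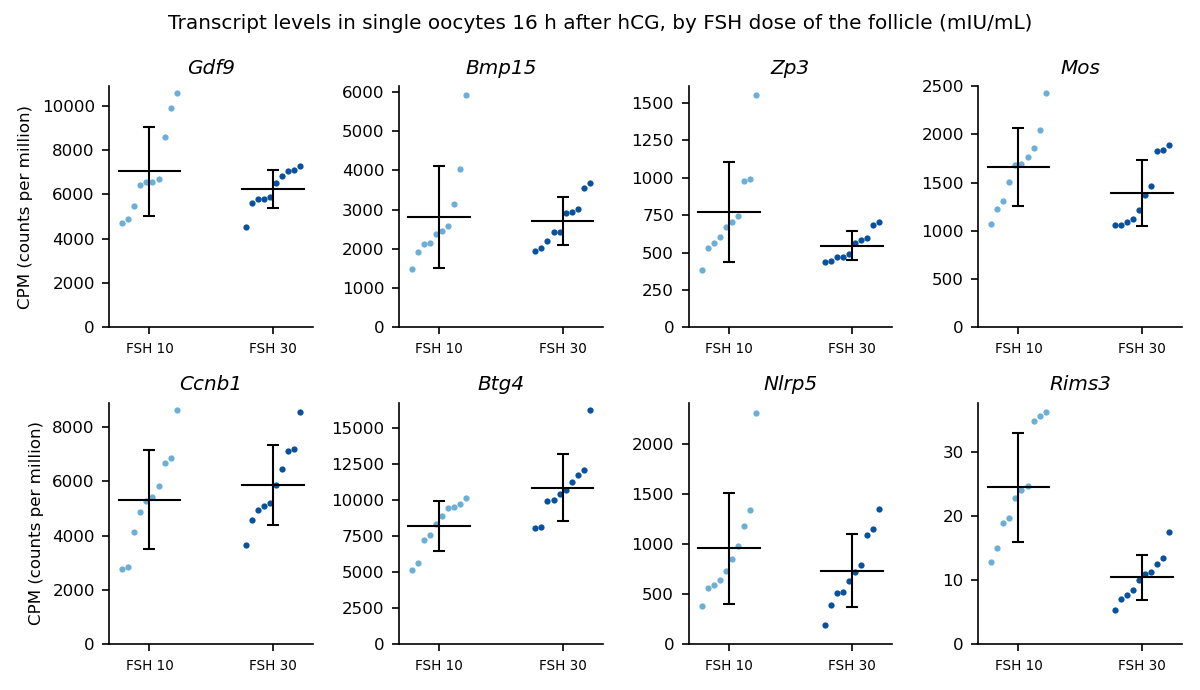
CPM of 8 genes in single oocytes 16 h after hCG by the FSH dose of the follicle in mIU/mL, 1 point per oocyte, with bars for the mean ± SD of 10 oocytes. The adjusted p of these genes ran from 0.183 for Rims3 to 0.92 for Bmp15.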

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

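Chosen only after the results were seen were the tests of ribosomal protein transcripts without 3 oocytes, the counts at an unadjusted p with their splits in follicles, and the tests on theca genes and on cell cycle genes, although the covariate of the latter was a setting fixed beforehand.

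In 15 of 85 combinations of a group with a library measure or a gene, 1 library lay far from the others of its group. The same libraries recur across these combinations. Chance gives about 1 in 20 only for independent, normally distributed values, so that an excess is not shown. Day 6 FSH 30 replicate 6 had 16664 detected genes against 18872 to 19690, and day 6 FSH 20 replicate 2 a TMM factor of 0.9606 against 0.9793 to 0.9884. Day 6 FSH 20 replicate 8 stood above its group in Cyp11a1 (576.5 CPM against 187.1 to 331.6), Star (119.5 CPM against 25.82 to 57.06) and Cyp17a1 (364.9 CPM against 77.37 to 151.9). Day 6 FSH 10 replicate 7 had 7124 CPM of Inhba against 9352 to 10206, 19.09 CPM of Amh against 0 to 4.161 and 9.928 CPM of Pgr against 1.818 to 4.751. Fshr was at 68.36 CPM in day 4 replicate 8 against 127.7 to 155.3, and Cyp19a1 at 438.1 CPM in day 6 FSH 10 replicate 5 against 321.9 to 352.8. Amh was at 23.71 CPM in day 6 FSH 30 replicate 7 against 0.0939 to 6.091, and Pgr at 8.488 CPM in day 6 FSH 20 replicate 1 against 2.731 to 4.44. Among oocytes, Zp3 was at 1555 CPM in FSH 10 replicate 3 against 381.4 to 989.2, Btg4 at 16248 CPM in FSH 30 replicate 4 against 8039 to 12129, and Nlrp5 at 2311 CPM in FSH 10 replicate 15 against 378.4 to 1342.

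Ribosomal protein transcripts had a median log2 change of -0.461 in oocytes at FSH 30 against FSH 10. Over all 20 oocytes, the median lay at percentile 0 of 10000 lists matched on gene length or on GC content, each apart and each together with mean expression. The central 95% of these lists ran from -0.272 to 0.022 and from -0.318 to -0.058. Random lists hold mostly unrelated genes, whose medians vary less than those of genes that move together. With an estimated correlation the set test did not pass. The percentiles therefore cannot decide whether gene length or GC content was the whole cause. Across genes, which are not independent replicates, the log2 change correlated with GC content (Pearson's r = -0.46). The lists matched on GC content and mean expression had a median of -0.185. GC content may thus account for a part, but these lists do not tell it apart from expression level. Without the 3 oocytes that stood apart, all at FSH 10, the set test had an adjusted p of 0.05377 and the median was -0.21. That median lay at percentile 0.08 of lists matched on length and mean expression but 8.3 of those matched on GC content and mean expression. Gene length and GC content thus stay open, and what the 3 oocytes contributed is undecided. The FSH dose stays open as a biological explanation, untested apart from them.

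Cyp17a1, Insl3 and Aldh1a1 rose with dose, at a median slope of 1.063 per doubling (SE 0.26). The 12 stroma markers had a median slope of 0.007 (SE 0.133). The 3 genes were the members of the theca endocrine list that had risen, and both SE are over genes, not follicles. This comparison therefore cannot argue against a larger share of theca and stroma cells. The summed share of the stroma markers stood at 0.130 ± 0.0477% of the counts at 5 and 0.189 ± 0.0611% at 30 mIU/mL. Such cells stay open as a cause. Without the follicles with few detected genes, of which only the day 6 ones are in the dose trend, 3 of the 3 genes still passed. A change within theca endocrine cells, in number or in expression, stays open.

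Cell cycle transcripts had a median log2 change of -0.442 (median SE 0.119) from day 4 to day 6 at FSH 5, with 21 of 27 lower. Without the 4 follicles with few detected genes 23 were lower, which argues against those follicles as the cause. With the number of detected genes as a covariate the median was -0.388 (median SE 0.13) and 27 of 27 had a negative sign, but 4 were called lower, with a smaller change and a wider error. That number is thus argued against as the whole cause, while a part of the pattern may go with it. Time in culture stays open as a biological explanation.

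Other splits of the libraries, 100 per comparison with the real one, showed where chance, meaning a random assignment of single libraries, can be excluded. They cannot exclude differences between animals, since the labels do not say which animal each library came from. From day 4 to day 6, 2 splits gave as many genes (real 1082, highest other 1155), and chance can be excluded at the 0.05 level. It can be excluded also where 1 split, the real one, gave as many, namely at 10 against 5 mIU/mL (752, highest other 167), 20 against 5 (1561, 172), 30 against 5 (2152, 410), 30 against 10 (30, 3) and in the trend (2677, 556). At 20 against 10 mIU/mL, 1 split gave as many as the 2 genes at an adjusted p (highest other 0), but 15 splits gave as many at an unadjusted p (real 625, highest other 1119), where chance cannot be excluded. At 30 against 20 mIU/mL and in oocytes the real count was 0, so that 100 of 100 splits gave as many by construction, which says nothing about chance (highest other 2 and 121). At an unadjusted p, 9 splits gave as many at 30 against 20 mIU/mL (real 756, highest other 1047), where chance cannot be excluded. In oocytes 3 splits gave as many (real 1733, highest other 2275), so that a random assignment of single oocytes can be excluded at the 0.05 level. No oocyte gene passed after adjustment, and the oocytes that stood apart were all at FSH 10. The excess at an unadjusted p therefore cannot be assigned to dose. The highest of the other oocyte splits gave 121, 75 and 46 genes against the real 0. At a threshold of 0.05 a few random splits can call genes by chance, many at once where genes move together. These splits therefore do not show a structure of the samples, which was not tested. Each of these splits kept 7 of 10 oocytes of a dose together, so that dose is not ruled out as a part of their calls.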

How the results depend on the processing

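The fits without the 4 follicles or the 3 oocytes and the counts at an unadjusted p were chosen after the results were seen. With a 2-fold minimum, the counts were 186 (day 6 against day 4), 175 (10 against 5 mIU/mL), 367 (20 against 5), 523 (30 against 5), 0 (20 against 10), 10 (30 against 10) and 612 (trend). With the number of detected genes as a covariate they were 313 (day 6 against day 4), 1019 (20 against 5) and 0 (20 against 10), and with the 12 libraries alone 93 (day 6 against day 4), 0 (20 against 10), 108 (30 against 10) and 13 (30 against 20). At 20 against 10, limma, the replicate block and the fit without the 4 follicles gave 0 each, and an unadjusted p 625. At 30 against 10, DESeq2 gave 92 and the fit without the 4 follicles 100; at 30 against 20, the fit without them gave 1 and an unadjusted p 756. In oocytes, DESeq2 gave 111, an unadjusted p 1733 and the replicate block 1. Of 89 list tests, 24 passed with an estimated correlation and 43 with fry. Leaving out each library gave 534 to 2154 genes (day 6 against day 4), 411 to 955 (10 against 5), 1002 to 1773 (20 against 5), 1643 to 2421 (30 against 5), 0 to 2 (20 against 10), 8 to 52 (30 against 10), 0 to 0 (30 against 20), 2035 to 2831 (trend) and 0 to 36 (oocytes). The fits with fewer libraries differ by construction, and for the others the cause was not tested. Of 303 calls on named genes, 0 reversed under any alternative, while 64 were lost (161 kept) with the 12 libraries alone, 56 with limma, 52 with the covariate, 52 with the replicate block, 42 without the 4 follicles, 17 (60 kept) with dose on the linear scale, 13 with no filter on low counts and 1 each with DESeq2 and RLE size factors. The labels do not say whether equal replicate numbers pair the libraries, and no pairing was detected. Same-numbered libraries had a mean correlation of 0.001 in follicles (highest 0.23) and -0.045 in oocytes (highest 0.184). Of 30 follicles 6, and of 14 oocytes 2, correlated best with their own number. The depth limits genes near 0.0741 CPM in follicles and 0.0916 CPM in oocytes, the worth of 1 read.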

Other observations

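Chosen only after the results were seen were the gene families, the comparisons of spread between oocytes and both tests of dose ranges.

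Gene families defined by symbol added groups that the fixed lists did not hold. From day 4 to day 6 at FSH 5, 6 of 17 aminoacyl-tRNA synthetase genes, which charge tRNAs with amino acids, fell and 0 rose (set test adjusted p = 4.2e-06, adjusted p = 0.16 with an estimated correlation), and 4 of 23 semaphorin and plexin genes rose (0.0021, adjusted p = 0.16 with an estimated correlation). Along the dose, 63 of 341 zinc finger genes of the Zfp series fell and 3 rose (1.7e-08, adjusted p = 0.069 with an estimated correlation), and 8 of 17 genes of the vacuolar proton pump rose (0.0084, adjusted p = 0.29 with an estimated correlation). Of 8 Wnt ligand genes 4 rose, Wnt4, Wnt5a, Wnt6 and Wnt10b (0.0055, adjusted p = 0.069 with an estimated correlation), and of 52 Rab genes, which direct vesicle traffic, 10 rose and 1 fell (0.0036, adjusted p = 0.069 with an estimated correlation). The medians of these families had the same sign under TMM, RLE and log2(TPM + 1). The counts by limma on log2(TPM + 1) differed: 3 aminoacyl-tRNA synthetase genes fell, 6 semaphorin and plexin genes rose, 89 Zfp genes fell and 3 rose, 3 proton pump and 3 Wnt genes rose, and 7 Rab genes rose and 2 fell. In all, 20 families were tested in 3 follicle comparisons and 18 in oocytes, and not all that passed are given. Rab and proton pump genes also rose from day 4 to day 6 at FSH 5, 5 of 52 and 3 of 18 (set test adjusted p = 0.0045 and 0.0073, adjusted p = 0.16 for each with an estimated correlation). In oocytes, only mitochondrial ribosomal protein genes passed the set test, with 0 of 73 passing singly (median log2 change -0.294, adjusted p = 0.0024, adjusted p = 0.52 with an estimated correlation).

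Oocytes at FSH 10 lay farther from the mean of the others of their group than those at FSH 30. The mean distance was 0.947 ± 0.151 against 0.834 ± 0.054 (SD, n = 10, permutation p = 0.03192, two-sided). The finished distances were shuffled without taking the group means anew. Distances within a group are not independent, so that the permutation p-values here are approximate. Without the 3 oocytes that stood apart, the distance at FSH 10 was 0.887 ± 0.126 (n = 7, exact permutation p = 0.2582). All 3 were at FSH 10, so that leaving them out narrows that group, and the lost call decides nothing.

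The LH-response and luteal list and the FSH-induced granulosa list may follow different dose ranges. From 10 to 30 mIU/mL, the mean log2 CPM of the first changed by 1.01 and that of the second by 0.18 (exact permutation p = 0.002165, two-sided, the smallest that 924 splits can give). From 5 to 10 mIU/mL, the changes were 0.91 and 0.97 (exact permutation p = 0.8095), which decides nothing. The prior count compresses the changes of low genes, and the mean level at 5 mIU/mL was 2.72 in the first list and 8.21 in the second.

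Oocyte libraries held transcripts of genes on the cumulus and granulosa list, with Serpine2 at 1690 ± 497 CPM at FSH 10 and 2079 ± 537 CPM at FSH 30 and Cyp19a1 at 61.5 ± 22.6 and 67.2 ± 21.4 CPM (SD, n = 10). The 12 genes other than Serpine2, Cyp19a1 among them, together took 0.00766 ± 0.00326% and 0.00745 ± 0.00225% of the counts. Inhba, also on the list, stood at 1.07 ± 2.05 and 0.89 ± 0.727 CPM. Whether these transcripts came from the oocyte or from cells around it was not tested.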
